A study of Mus musculus with 6 samples.

How the data were processed

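Total RNA of 6 cultures was labelled with Cy3 from 0.5 µg and hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. Each deposited file holds the scanner output of 1 array, with spot intensities that the authors made with Agilent Feature Extraction, version 10.7.1.1 per the file headers and 9.1 per the submitters' processing notes. The processed intensity was already background corrected, per the file headers, and was not scaled between arrays. The array design was made on mouse build mm9, per the file headers. The labels call the W4 ESC colonies feeder free, while the growth protocol describes growth on mouse embryonic fibroblast feeders and a short plating step to remove them.

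Values were log2 of the processed signal minus the array's 75th percentile over non-control spots (550 to 647 intensity units). Between 100 and 122 spots per array carried an outlier flag and were left out, and spots of a probe were averaged; 23 probes then lacked a value on an array and were dropped. The files name probes by accession; of 55681 probes, 26413 matched 1 symbol in a RefSeq table of assembly GRCm38.p6 and 29268 matched none and kept the file's name, so no coordinates are given. A gene was represented by its probe with the highest mean over the 6 arrays, and 107 of 3942 genes with several tested probes had probes called in both directions in MDSC versus ESC. A gene was tested if well above background on both arrays of at least 1 group, which left 25057 of 37153 genes and unnamed features, 15477 of them named.

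The 3 group means were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided), with 3 residual and 2.02 prior degrees of freedom. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. MDSC versus ESC is the mean of the WT and Mstn-null means minus the ESC mean. Where a gene was not well above background on any array of one side, a lower bound of the fold is given: the bright mean against the mean, per dim array, of the higher of that array's lowest well-above-background signal and the gene's own signal. Groups of 2 cannot give an exact permutation p below 0.333, so levels per array are given as values. The labels say that MDSC came from separate isolations, while the ESC arrays are separate passages of 1 line, whose spread may be smaller than between lines.

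Before the data were examined, 28 gene lists were fixed: pluripotency, early lineage, myogenic progenitor, muscle differentiation, fibroblast and matrix, endothelial, immune, pericyte and smooth muscle, Schwann and glial, adipocyte, bone and cartilage, germ cell, myostatin and activin pathway, TGF-beta response, BMP response, Wnt response, Notch response, cell cycle, cell cycle inhibitor, limb position and Hox, interferon response, MHC class I presentation, inflammatory secreted, imprinted growth, glycolysis, mitochondrial respiration, immediate early and stress, and Y-linked. Of their 594 entries, 585 had a probe. Some genes are in several lists, so results of lists that share members are not independent. Lists were tested with camera with a preset correlation of 0.01, adjusted over 112 tests of list and comparison, and again with an estimated correlation, with which no list passed. Counts adjusted over the list alone are given where they differ from those over all genes.

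Genes named by rule in MDSC versus ESC and in Mstn-null versus WT MDSC were, among genes past the threshold with no overlap between the arrays of the sides, the 5 largest rises and 5 largest falls among genes well above background on all arrays compared, and the 5 and 5 largest bounds among genes well above background on every array of one side and none of the other. Features without a gene name or with a provisional one were left out. Where fewer than 5 passed, those with the smallest p were named and said not to pass. Mstn and any list member could be named besides, and the list members given as examples were chosen after their values were seen.

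The steps were tested on simulated data with the real means and spreads and 200 changed genes. Among 25057 genes simulated for MDSC versus ESC, changes of 1, 2 and 4 on the log2 scale were called in 4 of 67, 36 of 67 and 55 of 66 genes. For Mstn-null versus WT MDSC they were called in 1 of 67, 26 of 67 and 47 of 66. Only 200 of 25057 genes changed there, whereas 14946 were called in the real MDSC versus ESC comparison. Noise was also drawn independently for each gene. The adjusted threshold depends on the share of changed genes, so these rates do not give the recovery in the real data.

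The alternatives tried were quantile normalization, median centring, normexp with an offset of 50 on the median and background signals (the deposited files give a median in place of the planned mean signal), no filter on dim probes, genes well above background on all arrays, outlier flags kept, the mean over the probes of a gene, only the groups compared, a variance trend with robust fitting, a 2-fold minimum, each array left out, and the isolation number as a replicate block. Tables were read and drawn with pandas and matplotlib.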

Results

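Gene expression was measured in 3 kinds of mouse cell, with 2 arrays for each kind. Muscle-derived stem cells (MDSC), the slowest adhering fraction of cells from hindlimb muscle, came from 5 week old male wild-type (WT) mice and from mice labelled null for Mstn, the gene of myostatin, a secreted inhibitor of muscle growth. Both were taken at passage 1, with 2 isolations each. W4, an established mouse embryonic stem cell (ESC) line, was taken at passages 12 and 15. Each array held 59305 non-control spots, of which 53.3% to 64.6% were well above background, and no spot was saturated. Values are log2 signals relative to each array's 75th percentile, and the number of arrays limits their precision. Across genes, the 2 arrays of a group correlated with r of 0.977 to 0.987, WT with Mstn-null MDSC with r of 0.955 to 0.978, and MDSC with ESC with r of 0.805 to 0.847. Genes are not independent replicates, so these values only describe the arrays.

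The probe of Mstn (A_51_P384901) was well above background on both arrays labelled Mstn-null and on no other array. Its log2 signal was -3.06 and -2.47 on the arrays labelled Mstn-null, -4.90 and -6.71 on the WT arrays, and -7.23 and -6.85 on the ESC arrays. Mstn was thus at least 4.07-fold higher on the arrays labelled Mstn-null than on the WT arrays (limma, adjusted p = 0.135), which did not pass the threshold, and at least 5.01-fold higher than on the ESC arrays (adjusted p = 0.00502). The probe thus showed no loss of signal on the arrays labelled Mstn-null. It was well above background on neither WT array, so it could not have shown a loss against them. Neither the allele nor the place of the probe relative to the deleted part is given in the sources used here, and a probe outside that part checks nothing. The groups are called by their labels below, and every direction between them rests on those labels.

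The first comparison asked how MDSC of both genotypes differ from ESC, as the stated purpose was to describe the potency of these cells by their expression. MDSC had very low signals for genes of the pluripotent state and high signals for matrix, inflammatory and limb position genes. Among named genes well above background on all 6 arrays, the largest falls in MDSC were those of Dppa5a (log2 difference -12.39 ± 0.24, SE, n = 4 and 2 arrays, limma adjusted p = 4.68e-05), the threonine dehydrogenase gene Tdh (-11.24 ± 0.28), the nuclear receptor gene Esrrb (-9.05 ± 0.40), Fbxo15 (-9.01 ± 0.18) and Rhox5 (-8.76 ± 0.36). The largest rises were those of Sod3, an extracellular superoxide dismutase (10.76 ± 0.55), Cck (8.77 ± 0.77), Thbs4, a matrix thrombospondin (8.73 ± 0.78), the chemokine gene Cxcl5 (8.04 ± 1.40) and Ptx3 (7.52 ± 1.12). These 10 genes had adjusted p between 4.68e-05 and 0.00693, with no overlap between the MDSC and ESC arrays.

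Other genes were well above background on one side alone, so their fold is a lower bound. L1td1 was at least 2831-fold higher in ESC, the pluripotency factor gene Pou5f1 at least 1939-fold, Zfp42 at least 1762-fold, Bex4 at least 1164-fold and the growth factor gene Fgf4 at least 1100.3-fold. On the MDSC side, Lilrb4a was at least 282-fold higher, the chemokine gene Ccl6 at least 206-fold, Ifi211 at least 164-fold, Esm1 at least 155-fold and the chemokine gene Ccl11 at least 111-fold. The arrays measured whole cultures, in which immune genes also rose, as given below. These folds therefore do not show which cells of the MDSC cultures carried the transcripts. Over all 25057 genes and unnamed features tested, 7086 were higher and 7860 lower in MDSC (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). The balance turned with the scaling, to 7165 higher and 6191 lower with median centring and 7759 and 7402 with quantile normalization.

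Of 39 tested pluripotency genes, 35 fell and 1 rose in MDSC. Their median log2 difference was -7.93, or -7.19 with one-sided members at their bound (camera adjusted p = 7.78e-15, adjusted p = 0.246 with an estimated correlation). Utf1 (-6.19) and Lin28a (-5.30) were among those that fell, and Klf2, also used by other cells, differed by -2.59. Sox2 was well above background on both ESC arrays and on 1 of the 4 MDSC arrays. Nanog was the exception that rose, by 0.56 ± 0.13 (adjusted p = 0.0185). That rise was short of the 2-fold minimum. It was not checked whether the only probe tested reads Nanog alone. By that probe, Nanog was well above background on all arrays. Its call ended when any one of both Mstn-null arrays, WT replicate 1 or ESC replicate 1 was left out, with adjusted p from 0.0509 to 0.0719. Tbx3 differed by -0.69 (adjusted p = 0.0325) and lost its call without any one of the Mstn-null or ESC arrays (adjusted p from 0.0862 to 0.111), with median centring (adjusted p = 0.117) or without a filter on dim probes (adjusted p = 0.0514). Klf4 did not pass (0.12, adjusted p = 0.733). It passed at 0.57 without ESC replicate 1 (adjusted p = 0.0496), and stood at -0.34 without ESC replicate 2 (adjusted p = 0.161). Sall4 did not pass by its brightest probe (-0.14, adjusted p = 0.386), and stood at 0.0039 with median centring, whereas its other probes fell by 10.25 and 5.28 and the mean over its probes fell by 5.22. Of 14 germ cell genes, 12 fell and 0 rose (median -6.28, or -5.09 with bounds, adjusted p = 1.32e-06, adjusted p = 0.485 with an estimated correlation). Tex19.1 was at least 889-fold, the receptor gene Kit at least 64.5-fold and the germ cell helicase gene Ddx4 at least 59.9-fold higher in ESC.

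**Figure D1:**
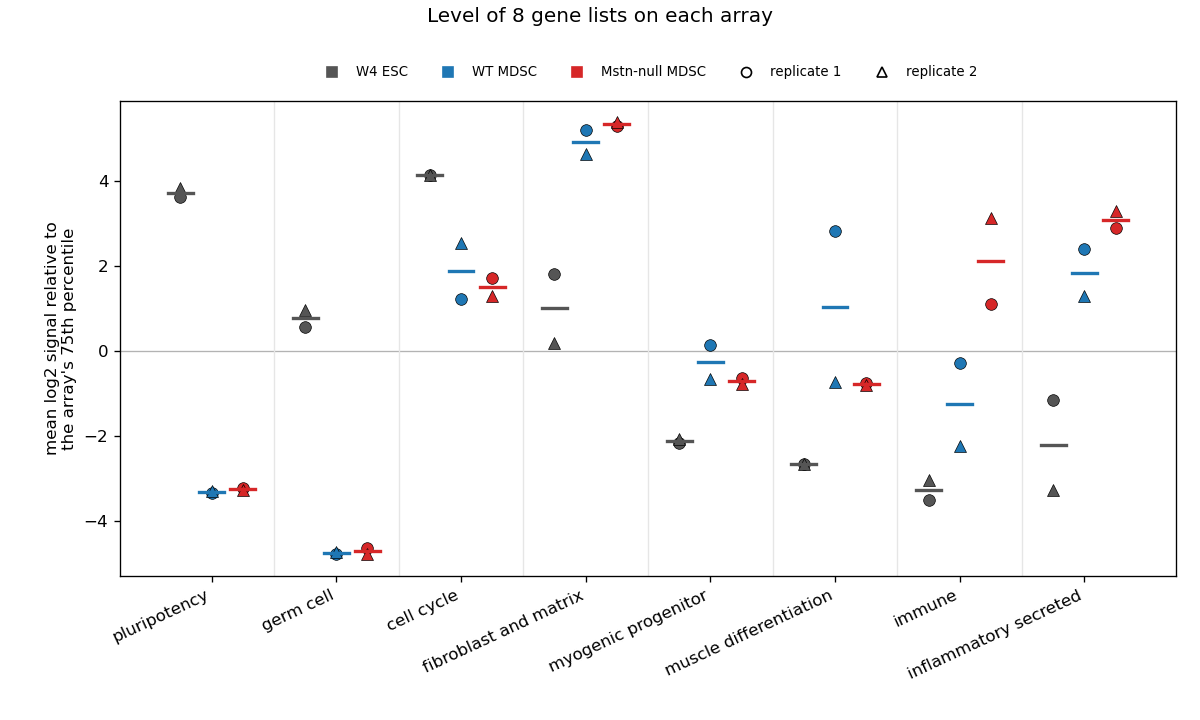
Mean log2 signal of 8 gene lists on each array, relative to the array's 75th percentile; each point is 1 array (circle, replicate 1; triangle, replicate 2) and each bar the mean of a group's 2 arrays. The pluripotency list lies at 3.61 and 3.83 on the ESC arrays and between -3.33 and -3.22 on the MDSC arrays, and the muscle differentiation list stands at 2.81 on WT replicate 1 alone.

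All 32 cell cycle genes had lower values in MDSC, and 29 of them fell, or 30 when adjusted over the list alone (median -2.45, adjusted p = 6.49e-07, adjusted p = 0.617 with an estimated correlation). The replication licensing gene Mcm2 differed by -3.48, the mitotic checkpoint gene Bub1 by -3.26 and the cyclin gene Ccne1 by -3.08. Of 15 cell cycle inhibitors, 8 rose and 2 fell, or 10 and 2 over the list alone (median 1.07, adjusted p = 0.0465, adjusted p = 0.485 with an estimated correlation). Cdkn2c rose by 4.78 and Cdkn1c fell by 3.30.

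Of 30 fibroblast and matrix genes, 27 rose and 0 fell (median 4.27, adjusted p = 1.60e-08, adjusted p = 0.485 with an estimated correlation). The collagen crosslinking enzyme gene Lox rose by 6.44, the receptor gene Pdgfrb by 5.23, the surface marker gene Ly6a (Sca-1) by 6.03 and the collagen gene Col1a1 by 4.16. The list's mean level was 1.82 on ESC replicate 1 and 0.20 on ESC replicate 2, against 4.63 to 5.37 on the MDSC arrays. Of 30 limb position and Hox genes, 25 rose and 2 fell (median 2.95, adjusted p = 6.22e-07, adjusted p = 0.246 with an estimated correlation). Hoxc10 was at least 57.9-fold and Hoxc11 at least 36.2-fold higher in MDSC, the hindlimb gene Pitx1 rose by 5.29, and Hoxd13 fell by 2.07. Of 21 inflammatory secreted genes, 17 rose and 0 fell, or 18 and 0 over the list alone (median 4.48, adjusted p = 8.56e-06, adjusted p = 0.505 with an estimated correlation). The cytokine gene Il6 rose by 7.36 and the chemokine gene Cxcl12 by 5.34. That list stood at -1.15 on ESC replicate 1 and at -3.27 on ESC replicate 2.

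Of 23 tested myogenic progenitor genes, 13 rose and 3 fell (median 1.61, adjusted p = 0.00812, adjusted p = 0.485 with an estimated correlation). Pax7, Myf5 and Myf6 of that list were not well above background on both arrays of any group. They were therefore not tested, and the median leaves them out. Myog, a factor of muscle differentiation, was at least 42.3-fold higher in MDSC, and Vcam1 rose by 4.62 and Sdc3 by 3.06. Myod1, a factor of muscle commitment, was at least 6.33-fold higher (adjusted p = 0.0127), but its call ended without ESC replicate 1 (adjusted p = 0.0631) or 2 (adjusted p = 0.0739), and with normexp (adjusted p = 0.0583). Calcr was at least 5.91-fold and Msc at least 3.18-fold higher in ESC, and Six4 fell by 1.62, a call that ended without WT replicate 1 and ESC replicate 1 together (adjusted p = 0.0679). Of 35 muscle differentiation genes, 19 rose and 1 fell (median 2.89, or 2.52 with bounds, adjusted p = 0.00142, adjusted p = 0.732 with an estimated correlation). Troponin gene Tnnt2 rose by 5.65 and the acetylcholine receptor gene Chrna1 by 5.35, and Mymx, a cell fusion gene, fell by 4.35. The list's mean level was 2.81 on WT replicate 1, -0.74 on WT replicate 2, and -0.76 and -0.79 on the arrays labelled Mstn-null.

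Markers of other cell types moved as well. Of 19 immune genes, 13 rose and 1 fell, or 15 and 1 over the list alone (median 3.35, adjusted p = 0.00139, adjusted p = 0.650 with an estimated correlation). WT alone against ESC did not pass (7 rose and 1 fell, or 6 and 1 over the list alone, median 1.99, or 2.05 with bounds, adjusted p = 0.0682), and the arrays labelled Mstn-null did (15 rose and 0 fell, median 5.14, adjusted p = 1.55e-05, adjusted p = 0.583 with an estimated correlation). The WT comparison passed without Mstn-null replicate 1 (0.0215) or 2 (0.0214), without WT replicate 2 (median 3.09, 0.0120) and with only the groups compared (0.0236). Without WT replicate 1 its median was 0.74 (adjusted p = 0.434). Lyz2 (8.42), Ctss (7.16) and Tyrobp (6.88), genes of macrophages and related cells, were well above background on all MDSC arrays and on 1 of 2 ESC arrays. Of 13 pericyte and smooth muscle genes, 9 rose and 2 fell, or 10 and 2 over the list alone (median 2.79, or 2.42 with bounds, adjusted p = 0.0277, adjusted p = 0.650 with an estimated correlation), with Cspg4 at 3.17 and Notch3 at -2.07. Of 16 adipocyte genes, 7 rose and 1 fell (median 2.17, adjusted p = 0.0130, adjusted p = 0.485 with an estimated correlation), and the lipase gene Lpl rose by 5.46. Of 13 bone and cartilage genes, 6 rose and 1 fell (median 2.06, or 2.02 with bounds, adjusted p = 0.0405, adjusted p = 0.485 with an estimated correlation). The cartilage matrix gene Comp rose by 7.24 and the tendon factor gene Scx by 5.19, and Tnmd, also of tendon, was at least 29.1-fold higher. The endothelial list did not pass (9 of 13 fell and 2 rose, or 9 and 3 over the list alone, median -1.92, or -1.91 with bounds, adjusted p = 0.0688). Cdh5 was at least 8.24-fold higher in MDSC, whereas Flt1 fell by 4.05 and Egfl7 by 2.75. The Schwann and glial list did not pass either (4 of 12 rose and 3 fell, adjusted p = 0.905). Its median was -0.06, from -0.52 to 0.69 with 1 array left out, and its mean 0.34, and S100b was at least 23.8-fold higher in MDSC.

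Signalling genes also differed, though their lists share members with lists above. The TGF-beta response list shares Col1a1, Fn1 and Lox with fibroblast and matrix, and Acta2 and Tagln with pericyte and smooth muscle. The myostatin and activin pathway list shares Dcn with fibroblast and matrix. Of 24 myostatin and activin pathway genes, 17 rose and 2 fell (median 2.07, adjusted p = 2.66e-04, adjusted p = 0.485 with an estimated correlation). The receptor gene Tgfbr2 rose by 4.19, Inhba by 2.77 and the myostatin antagonist gene Fst by 2.13 (1.33 without ESC replicate 2), and Acvr2b, a myostatin receptor gene, fell by 5.48. Of 20 TGF-beta response genes, 16 rose and 2 fell (median 2.58, adjusted p = 7.60e-05, adjusted p = 0.485 with an estimated correlation), with Ltbp2 at 5.14 and Tgif1 at -1.37. Of 14 BMP response genes, 10 rose and 0 fell (median 1.92, adjusted p = 0.00253, adjusted p = 0.485 with an estimated correlation), Id3 by 2.85 and Id1 by 2.06. The Wnt response list did not pass (7 of 19 rose and 6 fell, median 0.21, from -0.14 to 0.66 with 1 array left out, mean -0.18, adjusted p = 0.947). Sfrp1 rose by 4.15, and Sp5 was at least 119-fold higher in ESC. The Notch response list did not pass (2 of 14 rose and 7 fell, median -0.78, which was -0.42 without ESC replicate 1, adjusted p = 0.257).

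Of 21 interferon response genes, 7 rose and 0 fell, or 6 and 0 over the list alone (median 1.83, adjusted p = 0.0227, adjusted p = 0.754 with an estimated correlation). Of 15 MHC class I presentation genes, 10 rose and 1 fell (median 1.58, adjusted p = 0.0203, adjusted p = 0.669 with an estimated correlation), B2m by 2.68 and H2-D1 by 2.24. Of 16 immediate early and stress genes, 10 rose and 0 fell (median 2.15, adjusted p = 0.00427, adjusted p = 0.537 with an estimated correlation), Ier3 by 3.02 and Dusp1 by 2.45. The early lineage list did not pass (7 of 16 fell and 2 rose, median -2.20, or -1.60 with bounds, adjusted p = 0.0559). Gsc rose by 2.70, and T (brachyury) was at least 13.8-fold higher in ESC. The imprinted growth (3 of 15 rose and 6 fell, median -0.37, which was -0.62 without ESC replicate 1 and -1.09 without ESC replicate 2, adjusted p = 0.454), mitochondrial respiration (2 of 27 rose and 12 fell, median -0.34, adjusted p = 0.0839) and Y-linked lists (1 of 3 rose and 0 fell, median 0.08, from -0.19 to 0.39 with 1 array left out, adjusted p = 0.804) did not pass. The glycolysis list did not pass (3 of 21 rose and 5 fell, or 2 and 5 over the list alone, median 0.08, from -0.02 to 0.13 with 1 array left out, mean -0.42, adjusted p = 0.967). The glucose transporter gene Slc2a3 fell by 7.98 and Hk1 rose by 1.80. Gapdh did not pass (0.04, adjusted p = 0.857) and turned to -0.10 as the mean over its probes.

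The WT arrays lay alone on slide 1 and the other 4 arrays on slide 2, so slide and WT group cannot be told apart. Within slide 2, fitted on its own 4 arrays, 12353 of 14694 genes called in the pooled comparison and tested in both fits were called in the same direction and 4 in the opposite one, as were all 19 lists called. These 4 arrays also enter the pooled comparison, so the overlap is not independent of it. Within that slide, the pluripotency median was -7.89, the cell cycle median -2.69, the fibroblast and matrix median 4.49 and the immune median 5.14. Some list calls ended without 1 array, those of pericyte and smooth muscle (adjusted p = 0.0508) and MHC class I (adjusted p = 0.0523) without ESC replicate 1, and interferon response (median 1.07, adjusted p = 0.0883) without WT replicate 1. Bone and cartilage ended without Mstn-null replicate 1 (adjusted p = 0.0573), WT replicate 2 (adjusted p = 0.0596) or ESC replicate 1 (adjusted p = 0.0654), and cell cycle inhibitors without Mstn-null replicate 2 (adjusted p = 0.0664), WT replicate 1 (adjusted p = 0.0506), WT replicate 2 (adjusted p = 0.0697) or ESC replicate 1 (adjusted p = 0.0626). Early lineage passed without Mstn-null replicate 1 (adjusted p = 0.0478), Mstn-null replicate 2 (adjusted p = 0.0333) or ESC replicate 1 (adjusted p = 0.0125), and mitochondrial respiration without ESC replicate 1 (adjusted p = 0.0313). The endothelial list passed without Mstn-null replicate 1 (adjusted p = 0.0345), Mstn-null replicate 2 (adjusted p = 0.0499) or WT replicate 1 (adjusted p = 0.0304). With only genes well above background on all 6 arrays, the immune (adjusted p = 0.0858), germ cell (0.0609), pericyte (0.139), MHC class I (0.0609), interferon (0.184), bone (0.141) and cell cycle inhibitor (0.0736) calls ended, and mitochondrial respiration passed (0.0250). The cell cycle inhibitor call also ended with quantile normalization (adjusted p = 0.0623), median centring (0.0541), no filter on dim probes (0.0628) or the mean over probes (0.0608), and the bone call with quantile normalization (0.0524), no filter (0.0855) or the mean over probes (0.0562). Early lineage passed with median centring (0.0260) or no filter (0.0219), endothelial with median centring (0.0386), no filter (0.0226) or the mean over probes (0.0345), and mitochondrial respiration with normexp (0.0330) or no filter (0.0185).

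Each genotype was then compared with ESC by itself. WT MDSC had 6792 genes higher and 6502 lower than ESC, and the arrays labelled Mstn-null had 5849 higher and 7725 lower (limma). For the latter, 43.1% of calls were higher, and 53.3% with each array centred on its median (6253 higher and 5473 lower). Without Mstn-null replicate 2, 3636 were higher and 4345 lower. Besides the immune list, MHC class I (adjusted p = 0.0609), pericyte and smooth muscle (0.0563) and cell cycle inhibitors (0.0684) missed the threshold in WT and passed on the arrays labelled Mstn-null (0.00591, 0.0151 and 0.0314, or 0.617, 0.617 and 0.485 with an estimated correlation). Early lineage (0.0277, or 0.537 with an estimated correlation) and endothelial (0.0418, or 0.583) passed in WT and not on the arrays labelled Mstn-null (0.0882 and 0.151). Each of these 5 WT calls changed under some of the alternatives, and a missed threshold on one side does not show a difference between genotypes.

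The last comparison asked whether MDSC labelled Mstn-null differ from WT MDSC. By limma 0 genes were higher and 0 lower, although 3671 of 25057 had an unadjusted p under 0.05, and quantile normalization called 11 higher and 14 lower. A crossed replicate block, which pairs unlike isolation numbers, also called genes, and its counts are given below with the other alternatives. It was chosen after the data were seen, and the isolation numbers are not stated to pair samples. The genes named by smallest p did not pass. Those with higher values on the arrays labelled Mstn-null were Npy (log2 difference 3.51 ± 0.27, SE), Col28a1 (3.19 ± 0.26), Fxyd2 (2.67 ± 0.23), Cuedc1 (2.41 ± 0.20) and Alpk1 (1.79 ± 0.16), each with adjusted p = 0.0554. Those with lower values were Serinc2 (-3.84 ± 0.36, adjusted p = 0.0564), Prim2 (-3.72 ± 0.27), Zfp985 (-2.42 ± 0.18), Cyb561 (-2.00 ± 0.17) and Lmo7 (-1.76 ± 0.16). Among genes well above background on one side alone, Gbp2b was at least 11.7-fold, Pitpnm3 at least 9.77-fold, Dcstamp at least 5.93-fold, Cd207 at least 2.77-fold and Ceacam16 at least 2.54-fold higher on the arrays labelled Mstn-null. Cldn34c1 was at least 5.80-fold, Vmn2r15 at least 2.50-fold, Hbb-bh2 at least 2.37-fold, Aadacl2fm1 at least 2.05-fold and Defa42 at least 1.44-fold higher on the WT arrays (adjusted p from 0.0548 to 0.0554 over both sides). With quantile normalization, Col28a1, Fxyd2, Pitpnm3, Dcstamp, Cd207, Ceacam16, Prim2, Zfp985, Cyb561, Vmn2r15, Hbb-bh2 and Aadacl2fm1 passed, with adjusted p from 0.0311 to 0.0496. Of the other genes named here, Npy and Gbp2b passed with the crossed replicate block.

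No member of any list passed over all genes in the main fit of this comparison. With the crossed replicate block, the immune genes Tyrobp and Adgre1 did. The immune list had higher values on the arrays labelled Mstn-null, with 14 of 19 members higher when adjusted over the list alone (median 3.87, or 3.62 with bounds, camera adjusted p = 7.78e-15, adjusted p = 0.485 with an estimated correlation). The values were 4.29 for Tyrobp, 4.14 for Lyz2, 3.92 for Ctss, 3.57 for Adgre1, 3.47 for Ptprc and 2.30 for Csf1r. Spi1, a factor of macrophages and related cells, was at least 5.77-fold higher, and Itgam stood at -0.21 by its brightest probe and at 0.79 as the mean over its probes. The list's mean levels were 1.11 and 3.13 on the arrays labelled Mstn-null, -0.28 and -2.23 on the WT arrays, and -3.51 and -3.03 on the ESC arrays. Without Mstn-null replicate 2 the list's median was 2.56 and Csf1r stood at 1.44. The inflammatory secreted list was also higher (20 of 21 members positive, median 0.88, adjusted p = 4.22e-05, adjusted p = 0.515 with an estimated correlation), with 3.09 for Saa3, 2.85 for Ccl11, 1.54 for Ccl8 (0.98 without WT replicate 2) and 1.01 for Cxcl12 (0.66 without Mstn-null replicate 1).

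**Figure D2:**
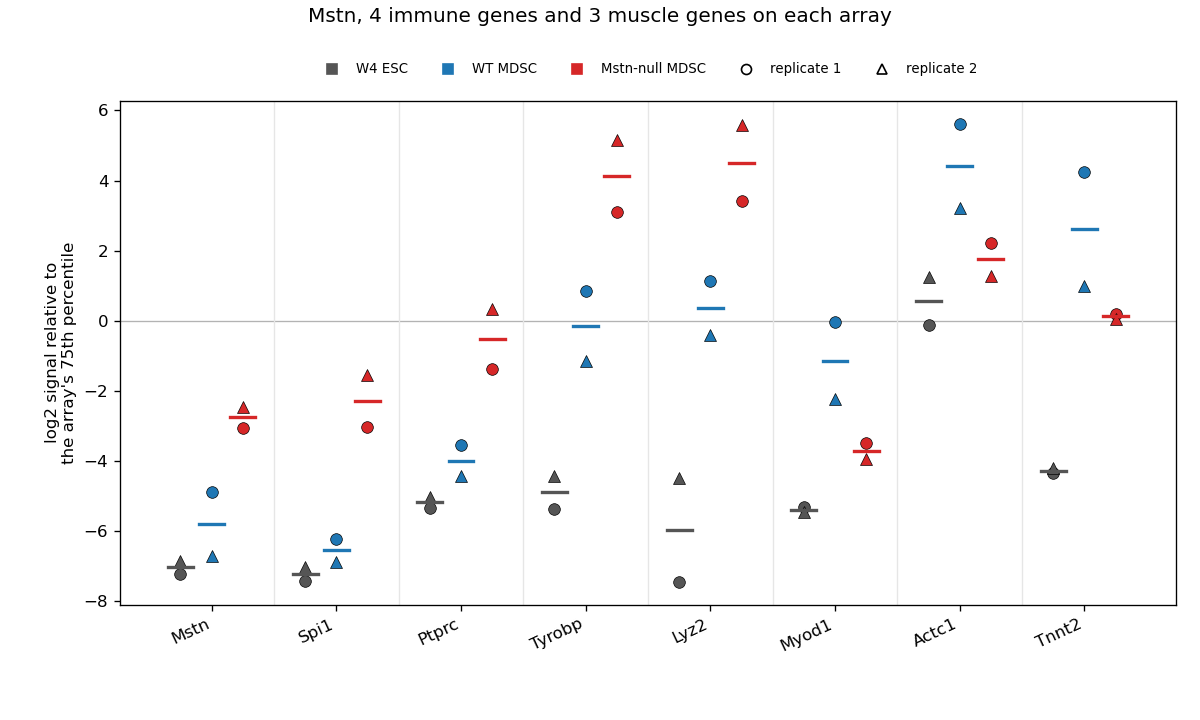
Log2 signal of Mstn, 4 immune genes and 3 muscle genes on each array, relative to the array's 75th percentile; each point is 1 array (circle, replicate 1; triangle, replicate 2) and each bar the mean of a group's 2 arrays. Mstn lies at -3.06 and -2.47 on the arrays labelled Mstn-null and at -4.90 and -6.71 on the WT arrays, and by group means Spi1, Ptprc, Tyrobp and Lyz2 are higher and Myod1, Actc1 and Tnnt2 lower on the arrays labelled Mstn-null.

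The muscle differentiation list was lower on the arrays labelled Mstn-null, with all 35 members negative (median -1.79, adjusted p = 5.93e-04, adjusted p = 0.722 with an estimated correlation). The values were -2.67 for the actin gene Actc1, -2.50 for Tnnt2, -2.32 for the embryonic myosin gene Myh3 and -1.70 for Myl1. Without WT replicate 1 the list's median was -0.13 (adjusted p = 0.544, within a range of 1.49e-38 to 0.722 over all alternatives), Myl1 stood at 0.26, Actc1 at -1.47, Tnnt2 at -0.87 and Myh3 at -0.89. Without WT replicate 2 the list's median was -3.71, and Myl1 stood at -3.66, Tnnt2 at -4.13 and Myh3 at -3.75. The myogenic progenitor list did not pass (15 of 23 members negative, median -0.14, or -0.22 with bounds, adjusted p = 0.924), and it passed without WT replicate 2 (median -0.27, adjusted p = 0.00973). Myod1 stood at -2.57, Myog at -2.53 and Cdh15 at -2.08, which were -1.47, -1.53 and -0.86 without WT replicate 1, and Cxcr4 was at least 4.53-fold higher on the arrays labelled Mstn-null.

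Smaller shifts passed with the preset correlation in 7 further lists, and each was lost with an estimated correlation. The fibroblast and matrix list was higher (median 0.23, adjusted p = 0.00184, adjusted p = 0.583 with an estimated correlation), as were the myostatin and activin pathway (median 0.32, adjusted p = 0.00253, adjusted p = 0.485 with an estimated correlation) and MHC class I presentation (median 0.24, adjusted p = 0.00427, adjusted p = 0.617 with an estimated correlation). The TGF-beta response (median 0.36, adjusted p = 0.00738, adjusted p = 0.505 with an estimated correlation), immediate early and stress (median 0.30, adjusted p = 0.0130, adjusted p = 0.583 with an estimated correlation) and Notch response lists (median 0.25, or 0.13 with bounds, adjusted p = 0.0133, adjusted p = 0.493 with an estimated correlation) were higher too. The mitochondrial respiration list was lower (median -0.24, adjusted p = 0.0418, adjusted p = 0.758 with an estimated correlation). In these pathways Acvr2a stood at 0.90, Tgfbr2 at 0.89, Fst at 0.77, Acvr2b at 0.34, Mfng at 1.54 and Jag1 at 0.88. Without WT replicate 2, Acvr2a stood at 0.33, Tgfbr2 at 0.46, Acvr2b at 0.0057 and Mfng at 2.70, and without Mstn-null replicate 2 Tgfbr2 stood at 0.56 and Mfng at 0.77. Without WT replicate 2, the medians were 0.06 for the myostatin pathway, 0.07 for TGF-beta response, 0.09 for immediate early genes, 0.06 for Notch response, -0.08 for MHC class I, -0.13 for mitochondrial respiration and 0.19 for fibroblast and matrix. Without that array, adjusted p was 0.0866 for fibroblast and matrix, 0.113 for the myostatin pathway, 0.261 for MHC class I, 0.332 for TGF-beta response, 0.311 for immediate early genes, 0.214 for Notch response and 0.174 for mitochondrial respiration. Without WT replicate 1, the medians were 0.39 for fibroblast and matrix, 0.59 for TGF-beta response, 0.66 for MHC class I, 0.73 for Notch response and 0.59 for immediate early genes. Without Mstn-null replicate 1 they were 0.18 for the myostatin pathway, 0.49 for MHC class I, 0.14 for Notch response and 0.18 for immediate early genes, and without Mstn-null replicate 2 they were -0.04 for MHC class I, 0.23 for TGF-beta response, 0.41 for Notch response and 0.49 for immediate early genes. MHC class I (adjusted p = 0.484) and TGF-beta response (0.0553) also ended without Mstn-null replicate 2, immediate early genes (0.138) without Mstn-null replicate 1 and Notch response (median 0.13, 0.0503) without ESC replicate 2. Mitochondrial respiration further ended without Mstn-null replicate 1 (0.0806), Mstn-null replicate 2 (0.0934) or WT replicate 1 (0.113), and with median centring (0.315), quantile normalization (0.131), only the groups compared (0.0501), the mean over probes (0.0503) or only genes well above background on all 6 arrays (0.0514).

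The other 17 lists did not pass. The pluripotency list had a median of 0.03, or -0.01 with bounds (adjusted p = 0.0849), with -0.05 for Nanog, which was 0.11 with median centring, and 0.07 for Sall4. Pou5f1 was not well above background on any MDSC array. The cell cycle list had a median of -0.37 (adjusted p = 0.326), which was -1.09 without WT replicate 1 (adjusted p = 2.34e-09) and 0.27 without WT replicate 2 (adjusted p = 5.84e-06). The interferon list had a median of -0.08 and a mean of 0.09 (adjusted p = 0.319), with a median of 1.05 without WT replicate 1 (adjusted p = 4.19e-07) and -0.99 without WT replicate 2 (adjusted p = 0.00847). Medians were -0.29 for limb position and Hox (adjusted p = 0.123), 0.54 for pericyte and smooth muscle (adjusted p = 0.0810), 0.25 for endothelial, or 0.17 with bounds (adjusted p = 0.171), and 0.17 for Wnt response, or 0.29 with bounds (adjusted p = 0.172). They were -0.56 for Schwann and glial (adjusted p = 0.367), -0.13 for BMP response (adjusted p = 0.519), -0.31 for imprinted growth (adjusted p = 0.502), 0.02 for germ cell, or 0.59 with bounds and a level for only 7 of 14 members (adjusted p = 0.164), and 0.31 for Y-linked (adjusted p = 0.0594). For early lineage (median -0.32, or -0.39 with bounds, adjusted p = 0.762), adipocyte (-0.19, 0.408), bone and cartilage (-0.13, or -0.10 with bounds, 0.953) and cell cycle inhibitor (-0.04, 0.762), the median was negative and the camera direction positive. Glycolysis had a median near 0 (0.00089, adjusted p = 0.284). With 1 array left out, medians ranged from -0.52 to -0.23 for limb position and Hox, -0.20 to 0.76 for pericyte, -0.18 to 0.69 for endothelial, 0.03 to 0.35 for Wnt, -0.81 to -0.32 for Schwann, -0.76 to 0.05 for BMP and -0.49 to -0.08 for imprinted growth. They ranged from -0.01 to 0.07 for germ cell, 0.11 to 0.51 for Y-linked, -0.38 to -0.21 for early lineage, -0.40 to 0.11 for adipocyte, -0.46 to 0.07 for bone, -0.13 to 0.06 for cell cycle inhibitor, -0.19 to 0.22 for glycolysis and 0.0022 to 0.05 for pluripotency. Calls appeared with 1 array left out: pericyte (adjusted p = 0.00263), endothelial (0.00816) and glycolysis (0.00667) without WT replicate 1, Schwann and glial (0.00973) without WT replicate 2, glycolysis (0.0236), interferon (0.0490) and Y-linked (0.0215) without Mstn-null replicate 1, endothelial (0.0214) and Y-linked (0.0148) without Mstn-null replicate 2, and limb position and Hox without ESC replicate 1 (0.0430) or 2 (0.0408). Wnt response passed with normexp (0.0344) or only genes well above background on all 6 arrays (0.0129), limb position and Hox with median centring (0.0260) or no filter on dim probes (0.0430), and Y-linked with normexp (0.0471). Meox1 was at least 15.3-fold and Lef1 at least 3.08-fold higher on the WT arrays, Nog stood at -2.19, Lpl at 2.09, Cd36 at 2.70, Cd34 at -1.31 (-0.44 without WT replicate 2) and Ly6a at -0.47 (-0.07 without it). Each of these comparisons of WT with Mstn-null arrays is also a comparison of slide 1 with slide 2.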

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

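The tests of a second macrophage list, of lymphocyte and neutrophil markers and of a second fibroblast list were set before their values were seen; the tests on slides, on WT replicate 1 and on early lineage genes in the ESC arrays were chosen after the result was seen, as were that on pluripotency genes in the ESC arrays and the verdict that the test of lymphocyte and neutrophil markers decides nothing. Differences between both genotypes relative to ESC are the Mstn-null versus WT comparison itself, and 10 lists passed there with the preset correlation. Their median log2 differences were 3.87 for immune, 0.876 for inflammatory secreted, -1.79 for muscle differentiation, 0.235 for fibroblast and matrix, 0.318 for the myostatin and activin pathway, 0.244 for MHC class I presentation, 0.364 for TGF-beta response, 0.298 for immediate early and stress, 0.248 for Notch response and -0.241 for mitochondrial respiration. None passed with an estimated correlation.

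Immune genes had higher values on the arrays labelled Mstn-null. Macrophages in those cultures are a candidate explanation: of 31 tested members of a second macrophage list, none of them in the fixed lists, 30 were above both WT arrays on both arrays labelled Mstn-null, with a median difference of 3.31, and its most abundant genes besides Lgals3 (-0.12) followed, among them Ccl9 (1.69), Mpeg1 (4.85) and Ms4a7 (4.41). Blood cells of other kinds stay open. The 16 lymphocyte and neutrophil markers had a median of 0.085, under the limit of 0.5 set against this beforehand. Most of them could not show a small share of such cells, so the test decides nothing. Of the 16, 7 had a level on the ESC arrays near or above that on the WT arrays. Another 4 were not well above background on both arrays of either MDSC group. Those 4 could still have shown a large rise, and they stood between 0.03 and 0.13. The other 5 went both ways. Il7r (4.23, well above background on only 1 WT array) and S100a8 (2.56) were higher, and Mpo (-0.10), Camp (-0.21) and Elane (-0.28) were not. The preplating steps select by adhesion, and no sort that would remove macrophages is described. A difference between slides cannot be told apart from the label, because WT lay alone on its slide; ESC arrays on the other slide were below WT by a median of -1.99 over the immune list, which does not settle it, and an effect of genotype stays open and untested.

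Muscle differentiation genes had lower values on the arrays labelled Mstn-null. The list's level was 2.81 on WT replicate 1 and between -0.79 and -0.74 on the other MDSC arrays. Without that array the median was -0.132, which follows from those levels and decides nothing. More differentiated muscle cells in that culture stay open. WT replicate 2 shared the slide and the genotype of WT replicate 1 but lay with the arrays labelled Mstn-null. Neither the slide nor the genotype alone therefore accounts for the level on WT replicate 1, and whether either adds to it stays open.

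Fibroblast and matrix genes were higher on ESC replicate 1 than on ESC replicate 2. Feeder fibroblast RNA is a candidate explanation, but the second fibroblast list differed by a median of 0.873 over 31 tested members, with 24 of them positive, which lay between the limit of 1 set for it and the limit of 0.3 set against it, so it stays open. Of its abundant genes, Pcolce (5.66 and 4.90) and Aebp1 (4.88 and 2.81), were higher on replicate 1 and Fkbp10 (3.78 and 4.32) was lower. The early lineage list was lower on replicate 1 by a median of -0.698, with 13 of 16 members negative. This gave no sign of more differentiation into the early lineages as a set on replicate 1. With 1 array per passage and a test chosen after the result was seen, it does not exclude such differentiation. The list pools several lineages, so its median cannot show differentiation into a single lineage, which stays open. Differentiation past those lineages stays open too, since the pluripotency list was also lower on replicate 1. Its median was -0.217, with 28 of 39 members negative and an upper quartile of 0.0136. Passage, which differs between both arrays, stays open and untested.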

How the results depend on the processing

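The crossed replicate block and the fit without WT replicate 1 and ESC replicate 1 together were chosen after seeing the data. Counts for MDSC versus ESC stayed within 1.5 times under every alternative run, from 5467 to 6500 higher and 6157 to 7352 lower with 1 array left out. With 1 array left out, counts ranged from 4910 to 5657 higher and 4478 to 5589 lower for WT versus ESC, 3636 to 5601 higher and 4345 to 7312 lower for Mstn-null versus ESC (lowest without Mstn-null replicate 2), and 0 for Mstn-null versus WT. Without both arrays in doubt, WT versus ESC had 4136 lower. Quantile normalization called 11 higher and 14 lower for Mstn-null versus WT. The isolation number as a replicate block called 0 and 0 and ended the mitochondrial respiration call (adjusted p = 0.126) and no other list call; the numbers are not stated to pair samples, and the deviations of same-numbered arrays correlated with r of -0.397 across genes. The crossed replicate block called 68 higher and 5 lower. The brightest spike-in control, E1A_r60_1, stood at 7.68 and 8.18 on the arrays labelled Mstn-null and at 8.42 and 8.33 on the WT arrays. The dim control E1A_r60_a104 went slightly the other way (-6.63 and -6.61 against -6.71 and -6.67). Scaling to such controls was not tried, so how the smaller shifts between Mstn-null and WT depend on it stays open. Median centring moved the median of all genes from -0.03 to 0.12 for MDSC versus ESC. For Mstn-null versus WT it moved that median from -0.12 to 0.04. All 168 list levels also moved by more than the replicate spread with median centring. Subtracting an array's median in place of its higher percentile shifts all its levels alike. That count therefore reflects the changed zero point and does not show how levels depend on scaling. Quantile normalization moved 30 of 168 levels by more than the replicate spread, and both counts cannot be compared. Of 1867 values of named genes under alternatives in MDSC versus ESC, 1803 kept direction and side of the threshold, and of 1068 in Mstn-null versus WT, 1044 did. These genes were named for extreme values or after their values were seen. In Mstn-null versus WT no gene passed in the main fit, so keeping the side there meant staying uncalled. The shares therefore do not measure how robust genes are in general. With an estimated correlation every list call ended. Over all alternatives, adjusted p for Mstn-null versus WT ranged from 3.17e-18 to 0.485 for immune, 1.82e-08 to 0.515 for inflammatory secreted, 2.34e-09 to 0.907 for cell cycle and 4.19e-07 to 0.876 for interferon. A lone array left in a group was assumed to vary like the others. Signal over background limits dim genes to bounds. Other causes were not tested.

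Directions turned as follows; for lists the camera direction turned and the median is given. In MDSC versus ESC, with quantile normalization Wnt stood at 0.22 and glycolysis 0.31. With median centring Sall4 stood at 0.0039 and Wnt 0.36. Without a dim filter Schwann stood at -0.0603, Wnt 0.075 and Y-linked -0.36. With genes well above background on all arrays early lineage stood at 0.42. As the mean over probes Gapdh stood at -0.098. Without both arrays in doubt Gapdh stood at -0.095 and Schwann -0.52. With 1 array left out Gapdh ranged from -0.058 to 0.13, Klf4 from -0.34 to 0.57, Schwann from -0.52 to 0.69, Wnt from -0.14 to 0.66, Y-linked from -0.19 to 0.39 and glycolysis from -0.018 to 0.13. In WT versus ESC, with quantile normalization glycolysis stood at 0.23. With median centring Y-linked stood at -0.33. Without a dim filter Schwann stood at 0.35. With genes well above background on all arrays early lineage stood at -0.022 and Wnt 1.48. Without both arrays in doubt Schwann stood at -0.30. With 1 array left out Schwann ranged from -0.11 to 1.12, Y-linked from -0.47 to -0.27 and glycolysis from -0.12 to 0.22. In Mstn-null versus ESC, with median centring Schwann stood at 0.40. With normexp glycolysis stood at 0.015. Without a dim filter Schwann stood at 0.18, Wnt 0.50 and glycolysis -0.00022. With genes well above background on all arrays early lineage stood at 0.66 and glycolysis -0.00022. Without both arrays in doubt Schwann stood at 0.30 and glycolysis -0.094. With 1 array left out Schwann ranged from -0.0301 to 0.435, Wnt from 0.22 to 0.87 and glycolysis from -0.13 to 0.13.

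In Mstn-null versus WT, with median centring Nanog stood at 0.11, early lineage -0.16 and bone 0.029. With normexp bone stood at -0.19. Without a dim filter bone stood at -0.15. With genes well above background on all arrays Schwann stood at -0.29, bone -0.19 and germ cell -0.44. As the mean over probes Itgam stood at 0.79. With only the groups compared early lineage stood at -0.37. Without both arrays in doubt Myl1 stood at 0.26, Nanog 0.0022, myogenic progenitor -0.052, muscle differentiation -0.13, bone -0.34 and imprinted -0.079. With 1 array left out Myl1 ranged from -3.66 to 0.26, Nanog from -0.10 to 0.0022, BMP from -0.76 to 0.045, adipocyte from -0.40 to 0.11, bone from -0.46 to 0.075, cell cycle inhibitor from -0.13 to 0.065, cell cycle from -1.09 to 0.27, early lineage from -0.38 to -0.21, endothelial from -0.18 to 0.69, glycolysis from -0.19 to 0.22, imprinted from -0.49 to -0.079, interferon from -0.99 to 1.05, muscle differentiation from -3.71 to -0.13, myogenic progenitor from -0.29 to -0.052 and pericyte from -0.20 to 0.76.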

Other observations

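The second macrophage list had mean levels of 0.453 and 2.42 on the arrays labelled Mstn-null, -1.21 and -2.49 on the WT arrays, and -3.22 and -3.34 on the ESC arrays. Among lymphocyte markers, Il7r stood 4.23 higher on the arrays labelled Mstn-null, but it was well above background on only 1 WT array. Cd3e (0.57), Nkg7 (0.03) and Cd4 (-0.30) differed less. Each of them had a level on the ESC arrays near or above that on the WT arrays, so they could not show a small share of lymphocytes. The neutrophil gene S100a8 stood at 2.56. None of these differences passed (limma, adjusted p from 0.126 to 0.948). The Mstn probe had its highest signals on the arrays labelled Mstn-null, but that difference from WT did not pass. Nanog, by the only probe tested, was well above background on all 6 arrays, and whether that probe reads Nanog alone was not checked.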
